A study of Homo sapiens with 12 samples.

How the data were processed

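CUT&RUN, in which an antibody on chromatin directs a nuclease to cut out the DNA it is bound to, was run on MKL-1, an established Merkel cell carcinoma line that carries Merkel cell polyomavirus. Per the labels, cells grew for 6 days with 3 µM EPZ011989, an inhibitor of the H3K27 methyltransferase EZH2, or with the 1% ethanol vehicle, and the medium was refreshed on day 3. Each culture was then divided between antibodies against H3K27me3, against H3K4me3 and control IgG, each used at a dilution of 1 to 100. The nuclease step lasted 30 min, and the stop buffer held E. coli DNA at 200 pg/mL as a spike-in. There are 12 libraries in 6 groups of 2 replicates. The series describes the treatment as done in duplicate on 1 cell line, so the spread between replicates covers repeated treatment and library making, not different tumours.

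The deposited data are 1 peak list per library on the hg38 genome build. Per the submitters' processing notes, the tools were FastQC, Bowtie2 2.2.9, SAMtools 0.1.19 and MACS2 2.1.1.20160309. The notes do not state the roles of the first 3 tools, the calling thresholds, the control library, the handling of duplicates or any use of the spike-in. The authors supplied broad peaks for H3K27me3 and narrow peaks for H3K4me3 and IgG. In the deposited lists each peak carries a MACS2 fold, a ratio of fragment pileup to a local background. Whether that background came from the same library or from a control is not known. Each peak also carries a −log10 p and a −log10 q by the authors' MACS2 run against that background. A score, which the authors' software derives from the −log10 q as a whole number, is given too. Spike-in values and counts of reads were not analysed here, so the true depth of each library is unknown and no scaling by spike-in was made. Folds were not compared between lists as they stand; where a peak was set against the depth of another library, its fold was first turned into fragments with its own library's background.

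A stand-in for depth was solved from each list, taking the background as the library's own. It used the most frequent fold in a list and the median −log10 p of the peaks with that fold. Under the Poisson model of MACS2 these fix a whole number of fragments and the background in fragments per base. This background ran from 0.0716 to 0.221 in the IgG libraries and from 0.148 to 1.63 in the antibody libraries. The peaks used to solve it held 4 to 10 fragments and need not be the weakest in a list. The solver was tested on simulated data in which each peak had a single whole-number pileup. Broad peaks, such as those of the H3K27me3 lists, were not simulated. Chance statements on what would be called at another library's depth rest on this estimate, and intervals on counts of peaks cover counting error only.

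Gene positions came from a table of the GRCh38.p14 assembly that gives no strand, and start sites could therefore not be told from gene ends. For each of the 19974 protein-coding genes on chromosomes 1 to 22 and X, a window of 2500 bp to each side of both gene ends was used in place of the start-site window planned before. The value of a gene in a library is the number of bases of this window inside the library's peaks, with no scaling between libraries. A gene was called marked with a peak overlapping its window by 1 bp or more. Gained means a H3K4me3 peak in both EPZ011989 libraries and neither vehicle library, and lost means the mirror image. Expanded means that both EPZ011989 values exceeded both vehicle values by 1000 bp or more, and contracted the mirror image; this pair of counts was added after the data were examined. Windows of neighbouring genes can share a peak, so genes are not independent replicates.

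Covered length was compared by exact two-sided permutation tests over the 6 labellings of 2 + 2 libraries, whose smallest possible p is 0.333. Covered bases per window were compared with limma 3.58.1 in R 4.3.3 (trend and robust), separately for each of the 2 marks, over genes with a peak in at least 1 of the 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fisher's exact tests, two-sided, related gains to vehicle H3K27me3 and compared each of 23 gene lists with all other genes, adjusted over the 23 lists. The position of the H3K27me3 peaks left with EPZ011989 was tested against 1000 circular shifts along each chromosome, one-sided. Exact Clopper-Pearson intervals at 95% accompany shares of peaks, and exact Poisson intervals accompany densities. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. Tested on simulated data, the limma test called 2 of 13125 unchanged H3K4me3 windows, 17 of 100 windows raised by 1000 bp and 73 of 100 raised by 2000 bp. For H3K27me3 it called 158 of 200 windows whose peaks had been removed and 8 of 9386 others. The simulation gave all 4 libraries the spread between the vehicle libraries. The EPZ011989 H3K4me3 libraries differed more in covered length, and in the data nearly all H3K27me3 windows lost their peaks. These rates therefore need not hold for the data.

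The gene lists, the tests, the settings to be varied and the rule for named genes were fixed before the data were examined. The rule names EZH2, EED and SUZ12 always, and not every gene that it names is given. It adds the 12 genes called lower in H3K27me3 with the largest summed length of vehicle peaks at their windows (1 per merged region), and the 12 gained and 12 lost H3K4me3 windows with the largest mean covered length. Up to 10 gained windows with vehicle H3K27me3, and 2 to 4 members per list with the largest difference, are also named. The 12 expanded windows with the largest difference were added after the data were examined. CASKIN2, TSEN54, the contracted genes, the HOXB members with peaks left, and the long noncoding RNA genes were named after their values were seen. Of 843 list entries, 842 matched a gene, 2 of them through an older symbol. Chromosome Y, mitochondrial and unplaced sequences were left out of the comparisons.

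The alternatives tried were a −log10 q of at least 5, peaks on IgG peaks left out, windows of 1000 and 5000 bp, an overlap of 500 bp, and all sequences in the lists. For limma they were log2 of covered bases plus 100, quantile normalization, subtraction of the median difference, no filter, no trend and the replicate number as a block. Each library was also left out in turn. A window at a single gene end, chosen without regard to treatment, and H3K4me3 peaks thinned to the solved background of the H3K4me3 library with the lowest one were added after the data were examined. The labels do not say that a replicate number is shared between treatments, so replicate numbers were not taken as pairs. Deviations of same-numbered replicates correlated at −0.0296 across genes for H3K4me3. For H3K27me3 the value was 0.0162, which says nothing about pairing, since nearly all windows had no peak in either EPZ011989 library.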

Results

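Peak lists of 12 CUT&RUN libraries of MKL-1 cells, 2 for each combination of treatment and antibody, were compared between EPZ011989 and vehicle. Vehicle H3K27me3 libraries held 40782 and 44287 peaks on chromosomes 1 to 22 and X, at a background of 1.12 and 1.63 fragments per base. EPZ011989 H3K27me3 libraries held 363 and 22 peaks at 0.373 and 0.148. The H3K4me3 libraries held 22726 and 23804 peaks in vehicle, at 0.572 and 0.857 fragments per base, and 23106 and 21086 with EPZ011989, at 1.48 and 1.24. In IgG libraries, the background of the assay, 38 and 4 peaks were listed in vehicle and 12 and 9 with EPZ011989.

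The first question was how much H3K27me3, the repressive histone mark that EZH2 writes, was left after EZH2 inhibition. H3K27me3 peaks covered 165 ± 15.1 Mb in vehicle and 0.112 ± 0.149 Mb with EPZ011989 (SD, n = 2 each), a vehicle-to-EPZ011989 ratio of 1466. The log2 ratio of EPZ011989 to vehicle, −10.52, was −14.48 without EPZ011989 replicate 1, −9.57 without EPZ011989 replicate 2 and −18.31 with the stricter q. The 2 EPZ011989 lists spanned 217 kb and 7.2 kb, and the 2 vehicle lists 154 Mb and 175 Mb. H3K4me3, a mark of active gene starts, covered 41.5 ± 0.713 Mb in vehicle and 42.6 ± 5.08 Mb with EPZ011989 (SD, n = 2 each), a difference smaller than the spread between replicates. IgG peaks covered 7.05 ± 8.36 kb in vehicle and 3.36 ± 0.612 kb with EPZ011989 (SD, n = 2 each). Exact permutation p-values were 0.333 for H3K27me3, the smallest that 2 + 2 libraries allow, and 1.0 for H3K4me3 and for IgG. The EPZ011989 H3K27me3 libraries also had the lower background coverage of that antibody. Without EPZ011989 replicate 1 the log2 ratio of H3K4me3 length went from 0.04 to −0.09, and without vehicle replicate 1 that of IgG length went from −1.07 to 1.56.

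**Figure D1:**
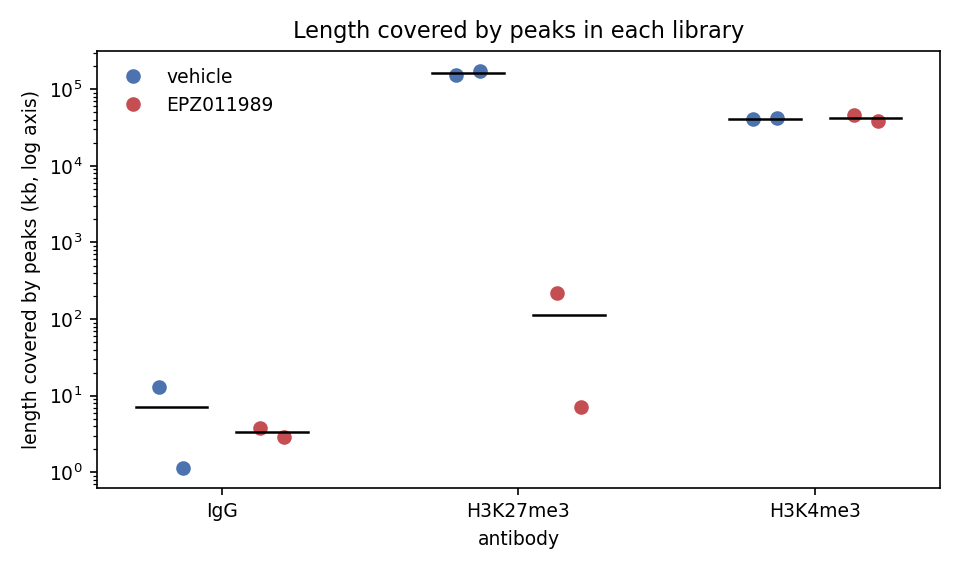
Length covered by peaks in kb on a log axis for each of the 12 libraries, by antibody, with a bar at each group mean of 2 libraries. The EPZ011989 H3K27me3 libraries lie at 217 and 7.2 kb, below both vehicle libraries, and the H3K4me3 libraries of the treatments overlap.

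At genes, the longest H3K27me3 region, merged over both vehicle libraries, was 698 kb on chromosome 17 from 48127992 to 48826185 and took in SKAP1, an adaptor of T cell adhesion. It also held HOXB1 to HOXB9 and HOXB13, homeobox genes of body-axis patterning. Other long merged regions lay over CCND2 and into TIGAR (450 kb), over the growth factor genes FGF19, FGF4 and FGF3 beside ANO1 (351 kb), over the cyclin gene CCND1 (334 kb) and over MSX2 (321 kb). At CCND1, on chromosome 11 from 69641156 to 69654474, H3K27me3 fell from 8802 and 10002 covered bp in the vehicle libraries to 0 in both EPZ011989 libraries (limma adjusted p = 0.00706). FOXC2 and FOXL1 lay in a merged region of 306 kb that reached MTHFSD, where the peaks at the window summed to 32.3 kb in vehicle replicate 1 and, with those of the FOXF1 region, to 566 kb in vehicle replicate 2. FOXF1 had one of 260 kb, and PRDM16, a regulator of brown fat, one of 202 kb. Immune genes were among them too: TNFSF9, CD70 and TNFSF14 in 271 kb of chromosome 19, and a group of SIGLEC genes beside ETFB in 236 kb. The 12 genes named for the summed length of the vehicle peaks at their windows also include CLC, in a merged region of 264 kb, and ZNF652, at one of 342 kb (190 kb and 345 kb of peaks at the window in vehicle replicates 1 and 2). The windows of all 12 fell to 0 covered bp in both EPZ011989 libraries. CCND2, which is not among the 12, kept 2669 of 10002 bp in EPZ011989 replicate 1 and 0 in replicate 2. EZH2, EED and SUZ12, which encode the core of the methyltransferase complex, carried no H3K27me3 peak in any library.

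Of 19974 genes, 7372 were marked in both vehicle libraries, and 7344 of these in neither EPZ011989 library; the mirror count was 0. EPZ011989 replicate 1 marked 39 genes. Replicate 2 marked 2, CASKIN2 and TSEN54, and no gene was marked in both. By limma, 5784 of 9601 genes tested were lower and 0 higher, with 6154 lower and 0 higher at an unadjusted p under 0.05. Quantile normalization, which forces the same distribution on every library, gave 3598 lower and 3301 higher, and no other setting except leaving out EPZ011989 replicate 2 (7 higher) gave a higher call. In 14.2% of the genes tested the replicates were identical within both groups, so that their p-values rest on a spread taken from other genes. At windows such as ANO1, which went from 10002 bp to 0, the standard error was 1.71e-05 bp (limma adjusted p = 2.11e-21). Such p-values reflect the ceiling and floor of the measure and not a spread between replicates. The lower count was 3211 without EPZ011989 replicate 1, 3210 without replicate 2 and 3301 with the stricter q.

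Developmental gene families were marked more often than other genes in vehicle, and most of their tested windows fell with EPZ011989. In this paragraph and the next, a window fell where limma called it lower. In the FGF, non-HOX homeobox, other transcription factor and neurogenic lists no member had a peak in either EPZ011989 library. Their tested windows that did not fall by limma had lost their peaks too. H3K27me3 was present in both vehicle libraries at 36 of 40 FGF and receptor tyrosine kinase genes (odds ratio 15.5, adjusted p = 2.94e-11). FGF3, FGF19 and IGF2 were covered over all 10002 bp of their windows, and 33 of 36 tested windows of the list fell. It was present at 56 of 71 other developmental transcription factors (odds ratio 6.42, adjusted p = 9.34e-12), among them the lineage regulators GATA3, GATA4 and SOX8, and 51 of 59 tested windows fell. Among non-HOX homeobox regulators 62 of 80 were marked (odds ratio 5.93, adjusted p = 5.57e-12). These included CDX2 of the gut and IRX4 of the heart ventricle over 10002 bp each, and 60 of 68 fell. Of the HOX genes 30 of 39 were marked (odds ratio 5.72, adjusted p = 1.93e-06). HOXC10, HOXC13, HOXD11 and HOXD13 were covered over 10002 bp each, and 25 of 32 fell. The 8 members with a peak in EPZ011989 replicate 1 all belong to the HOXB cluster. WNT pathway genes (33 of 42, odds ratio 6.29, adjusted p = 2.63e-07) included the ligands WNT3A and WNT10B, and 31 of 36 fell. BMP, TGF-beta and hedgehog genes (30 of 42, odds ratio 4.29, adjusted p = 2.66e-05) included SHH and the BMP antagonist CHRD, and 27 of 33 fell. Neurogenic and neuronal differentiation genes (24 of 33, odds ratio 4.57, adjusted p = 0.000118) included the neurotrophin receptor gene NGFR and the transporter gene SLC32A1 of inhibitory neurons, and 20 of 25 fell.

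The other lists marked more often than other genes were lists of immune recognition. No member of the HLA and natural killer ligand lists had a H3K27me3 peak in either EPZ011989 library. Their tested windows that did not fall by limma had thus lost their peaks too. HLA class II presentation genes were marked at 11 of 15 (odds ratio 4.71, adjusted p = 0.0128), with HLA-DRA, HLA-DPA1 and HLA-DPB1 covered over 10002 bp in vehicle, and 9 of 13 tested windows fell. As in the other list tests, neighbouring genes under 1 broad region count separately, and HLA-DPA1 and HLA-DPB1 overlap in position. Ligands of natural killer cells and immune checkpoints were marked at 16 of 25 (odds ratio 3.04, adjusted p = 0.0137), including MICA, a ligand of the activating receptor NKG2D, and the adhesion gene ICAM1, and 13 of 19 fell. No difference passed for HLA class I presentation genes (10 of 24 marked, adjusted p = 0.738); TAP1, TAP2 and PSMB9, which supply peptides to class I molecules, each had 10002 bp in both vehicle libraries, and 9 of 12 tested windows fell.

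The remaining lists split as follows. Protocadherin cluster genes (7 of 53, odds ratio 0.259, adjusted p = 0.000484) and housekeeping genes (4 of 32, odds ratio 0.244, adjusted p = 0.00776) were marked less often than other genes. No difference passed for Merkel cell and neuroendocrine markers (8 of 37), germline genes (7 of 30), cell cycle inhibitors and p53 targets (11 of 36), Polycomb and demethylase genes (11 of 34), skeletal muscle genes and their regulators (11 of 28), imprinted genes (11 of 25), interferon and chemokine genes (22 of 44), keratinocyte markers (16 of 31), lymphoid and myeloid markers (18 of 33), fibroblast markers (15 of 26) or endothelial markers (13 of 22). Counts of lower windows adjusted over the list alone were within 2 of those adjusted over all genes in each of the 23 lists. They were 34 for FGF and receptor tyrosine kinase genes, 61 for non-HOX homeobox regulators, 51 for other developmental transcription factors, 25 for HOX genes, 32 for WNT, 29 for BMP, TGF-beta and hedgehog, 20 for neurogenic genes, 10 for HLA class II, 14 for natural killer ligands and 10 for HLA class I. Under quantile normalization more windows were called higher than lower in 5 lists: interferon (14 against 10), Merkel cell (6 against 4), HLA class I (5 against 4), germline (4 against 3) and housekeeping (11 against 0).

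**Figure D2:**
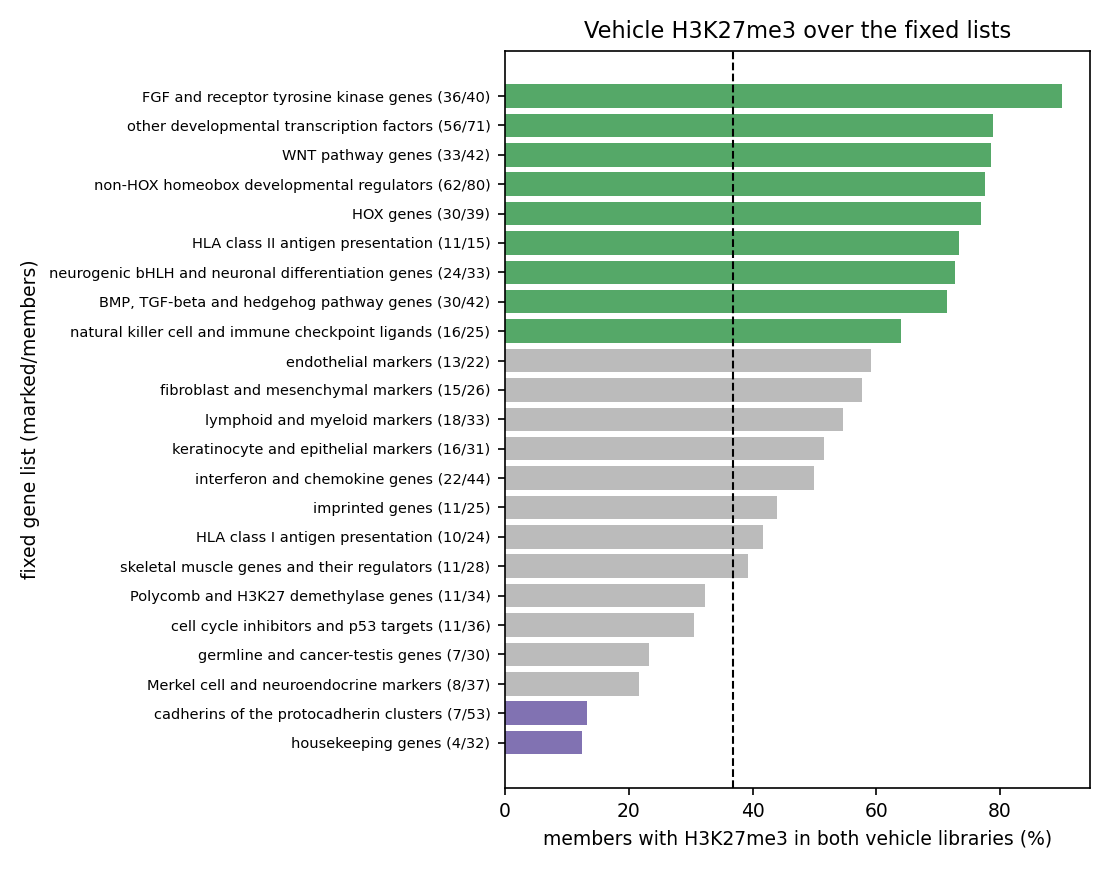
Percent of each fixed list's members with a H3K27me3 peak in both vehicle libraries, with members marked and members in brackets; the dashed line is the share among all genes. Green bars passed the adjusted Fisher test above the other genes (9 lists), purple bars below (2 lists), and grey bars did not pass.

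The few H3K27me3 peaks left with EPZ011989 were then set against the vehicle regions. In EPZ011989 replicate 1 the HOXB region kept 23 peaks of 30.2 kb in all, where vehicle replicates 1 and 2 had 696 kb and 698 kb covered. EPZ011989 replicate 2 had no peak there. Single genes with a peak left in replicate 1 included COL1A1, for a chain of the main collagen of bone and skin (2132 bp of 10002 bp in vehicle), and NOG, a BMP antagonist (1489 bp of 6913 bp). Of the 363 peaks in replicate 1, 66 lay on regions covered in both vehicle libraries, which is 18.2% (exact 95% interval 14.4 to 22.5), against 6.05% for shifted peaks (permutation p = 0.000999, the smallest that 1000 shifts allow). In replicate 2 it was 3 of 22, or 13.6% (exact 95% interval 2.91 to 34.9), against 6.34% (permutation p = 0.159), and 4 of the 22 lay on IgG peaks. With the stricter q no peak was left in replicate 1 and 2 in replicate 2, of which 0 lay on vehicle regions. Against vehicle replicate 1 alone, 22.7% of the replicate 2 peaks lay on vehicle regions (permutation p = 0.015).

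**Figure D3:**
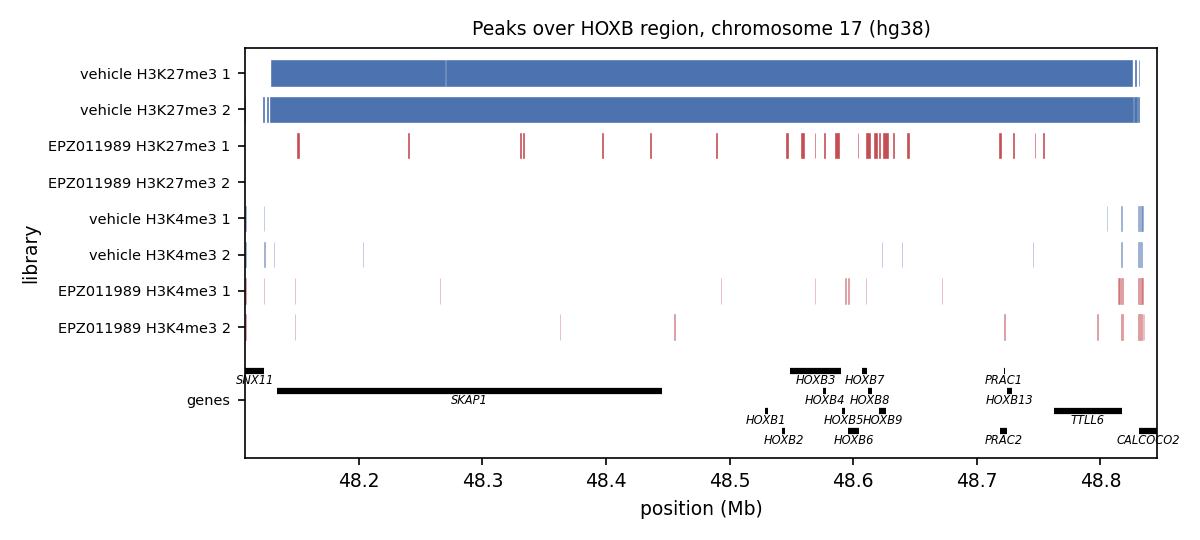
Peaks of the 8 H3K27me3 and H3K4me3 libraries across the HOXB region, as bars over position in Mb, vehicle in blue and EPZ011989 in red, with genes in black. The H3K27me3 regions of both vehicle libraries are missing with EPZ011989 except for 23 short peaks of replicate 1 in the HOXB region.

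The second question was whether H3K4me3 differed with EPZ011989, in particular at genes that carried H3K27me3. At HOXD11, a gene of limb patterning on chromosome 2 from 176107280 to 176115679, the H3K4me3-covered length was 1135 ± 368 bp in vehicle and 3900 ± 70.7 bp with EPZ011989 (SD, n = 2 each; limma adjusted p = 0.0735 over all genes, 0.00262 adjusted over the list alone). Other developmental genes with wider H3K4me3 included LHX1, of kidney and motor neuron development (1555 ± 383 to 4157 ± 663 bp), TBX2, a regulator of heart and limb development (4036 ± 38.2 to 6876 ± 548 bp), and NOG (2307 ± 525 to 5197 ± 298 bp). Others among the largest such differences were at GPR162, CALY, NAT16, MMP17, LOC124900252, GRXCR1 and RASGRP2.

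H3K4me3 peaks present in both EPZ011989 libraries and neither vehicle library lay at 184 genes. Those with long peaks included GRXCR1, a gene of hair cell bundles in the inner ear (2828 ± 175 bp, with no H3K27me3 in any library), RASGRP2, a Rap activator of platelets (2735 ± 191 bp), YPEL4 (1898 ± 674 bp), the blood lineage regulator GATA2 (1730 ± 844 bp) and LRFN1 (1683 ± 504 bp). TMEM132C, DIO3, AMN, SH3PXD2A, FBXO27 and DKKL1 followed. Apart from GRXCR1, all of these 11 carried H3K27me3 in both vehicle libraries and in neither EPZ011989 library. Peaks in both vehicle libraries and neither EPZ011989 library lay at 28 genes, the longest at TMEM278 (921 ± 24.7 bp), SMIM46 (717 ± 260 bp) and CAPN12 (677 ± 226 bp), followed by ANKRD2, MYMK, CD79B, C1QTNF3, OR6B2, ZNF124, C1orf116, CA7 and RBPJL. At the genes of the methyltransferase itself H3K4me3 was 4008 ± 79.2 and 3843 ± 289 bp for EZH2 in vehicle and EPZ011989, 3249 ± 33.9 and 3304 ± 277 bp for EED, and 2503 ± 203 and 2468 ± 850 bp for SUZ12, differences within the spread between replicates.

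**Figure D4:**
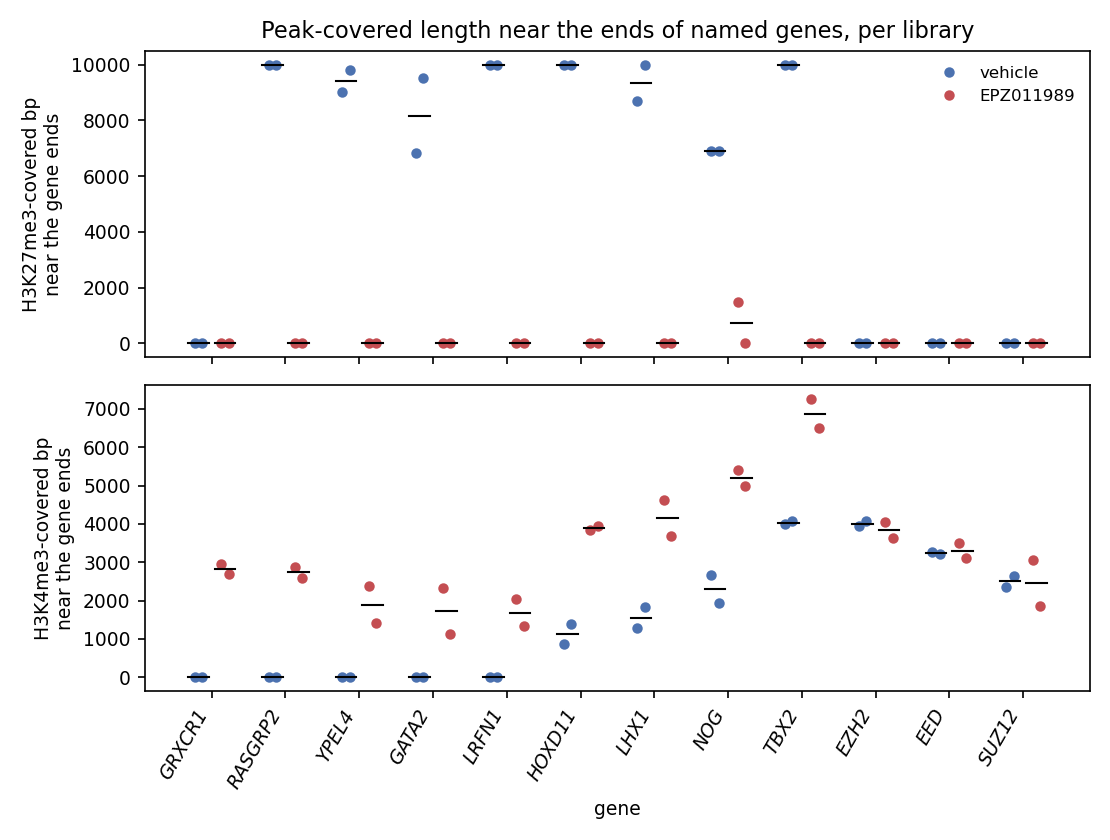
H3K27me3-covered (upper) and H3K4me3-covered (lower) bp near the ends of 12 named genes, 1 point per library, vehicle in blue and EPZ011989 in red, with bars at the means of 2 libraries. At HOXD11 the H3K4me3 means are 1135 and 3900 bp, and at EZH2, EED and SUZ12 the treatments overlap.

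By limma, 0 of 13796 genes tested for H3K4me3 were higher and 0 lower. At an unadjusted p under 0.05, 1160 were higher and 204 lower, and the smallest adjusted p was 0.0644. The median difference, 52.0 bp, depended on single libraries: it was −83.0 bp without EPZ011989 replicate 1 and 190 bp without EPZ011989 replicate 2. The same test gave 89 higher and 7 lower after quantile normalization, which moved the median difference from 52.0 to −40.5 bp and the unadjusted counts to 1030 higher and 784 lower. It gave 35 higher and 0 lower with windows of 5000 bp, 2 higher and 4 lower with windows of 1000 bp, and 491 higher and 32 lower with no filter, where 31.3% of genes had no spread within groups. The counts of gained and lost windows have no test of their own, and the other divisions of the 4 libraries give the level of chance differences. Pairing the replicates numbered 2 against those numbered 1 gave 9 and 35 genes, and EPZ011989 replicate 1 with vehicle replicate 2 against the others gave 41 and 10. Median H3K4me3 peak widths were 1453 and 1354 bp in the vehicle libraries and 1696 and 1609 bp in the EPZ011989 libraries. In a comparison added after the data were examined, over windows with a peak in all 4 libraries, the median difference in covered length between treatments was 205.5 bp at the 4803 with vehicle H3K27me3 and −24.5 bp at the other 8055. Against vehicle replicates 1 and 2, EPZ011989 replicate 1 gave 374 and 340 bp at the 4803, and replicate 2 gave 72 and 50 bp. At the 8055, replicate 1 gave 113 and 92 bp and replicate 2 −152 and −179 bp. The size at the 4803 thus rests largely on EPZ011989 replicate 1, and the sign at the 8055 depends on the replicate. Windows longer by 1000 bp or more in both EPZ011989 libraries numbered 148. Shorter ones numbered 5, at RSBN1L, DYNC1H1, PTBP1 and the neighbours SARS2 and MRPS12, and the other divisions gave at most 15. Without EPZ011989 replicate 2, 377 genes were gained and 672 expanded. Without EPZ011989 replicate 1, 116 were lost and 97 contracted, and the lost counts without vehicle replicates 1 and 2 were 84 and 66. The expanded counts without vehicle replicates 1 and 2 were 238 and 267, and the contracted counts 32 and 20.

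**Figure D5:**
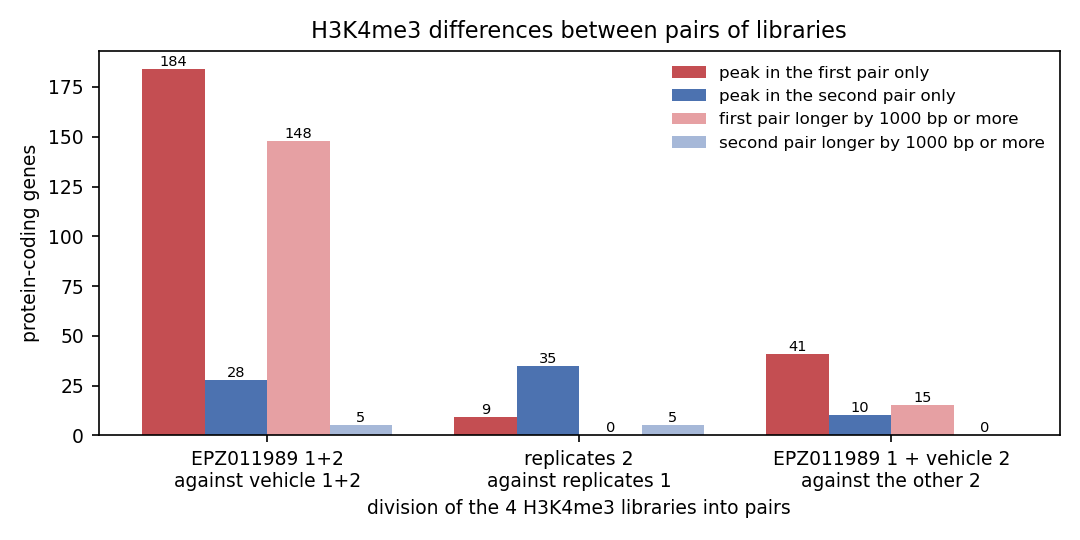
Number of protein-coding genes with H3K4me3 peaks in 1 pair of libraries only, or longer by 1000 bp or more in 1 pair, for each of the 3 ways to divide the 4 H3K4me3 libraries. The treatment division gives 184 and 148 genes for the EPZ011989 pair against 28 and 5 for the vehicle pair.

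Gains concentrated at genes that carried H3K27me3 in vehicle. Among the 6645 genes without a vehicle H3K4me3 peak, 178 of 2314 with H3K27me3 gained a peak (7.69%) and 6 of 4331 without it (0.139%), an odds ratio of 60.1 (Fisher's exact p = 1.3e-74, in which neighbouring genes that share peaks count separately). Genes with and without H3K27me3 were not matched for kind of gene. Of 392 olfactory receptor genes, for example, 77 carried H3K27me3 and 4 H3K4me3 in vehicle. Of the 178 genes that gained a peak and carried H3K27me3, 177 had it in neither EPZ011989 library. So had 7344 of all 7372 marked genes, so this does not set the gained ones apart. Of the 148 expanded windows 137 were marked in vehicle (odds ratio 19.6, Fisher's exact p = 9.7e-43), and of the 28 lost windows 7 (odds ratio 0.560, Fisher's exact p = 0.24). Of the 5 contracted windows 4 were marked (odds ratio 6.14, Fisher's exact p = 0.0829). The odds ratio for gains without single H3K4me3 libraries ran from 12.1 to 28.4, the lowest without EPZ011989 replicate 1. Of 4839 genes with both marks in vehicle, such as HOXD11 and TBX2, 4803 had H3K4me3 in both EPZ011989 libraries. For H3K4me3 peaks as a whole, the Jaccard index of covered bases was 0.785 between the vehicle libraries, 0.748 between the EPZ011989 libraries and 0.732 to 0.748 between treatments.

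Of the 7 developmental lists, 5 held more expanded windows than other genes, in a test added after the data were examined. These windows were 7 non-HOX homeobox regulators (odds ratio 13.2, adjusted p = 6.21e-05), 6 other developmental transcription factors (odds ratio 15.5, adjusted p = 6.96e-05), 4 HOX genes (odds ratio 12.2, adjusted p = 0.00394), 3 WNT genes (odds ratio 10.1, adjusted p = 0.024) and 3 BMP, TGF-beta and hedgehog genes (odds ratio 9.39, adjusted p = 0.024). No difference passed for neurogenic and neuronal genes (2 expanded, adjusted p = 0.126) or for FGF and receptor tyrosine kinase genes (1 expanded, adjusted p = 0.517). With H3K4me3 adjusted over the list alone, 13 of 58 homeobox regulators rose, among them LHX1, LMX1B and DLX3, where 0 passed over all genes. On the same terms 11 of 43 developmental transcription factors rose, including TBX2, SOX21 and ZEB2, and 6 of 35 HOX genes, including HOXD11, HOXD12 and HOXD13. So did 7 of 31 WNT genes, including WNT7A and FZD2, and 5 of 33 BMP, TGF-beta and hedgehog genes, including NOG, TGFB1 and FST. Neighbours that share peaks count separately in these numbers. HOXD11 and HOXD12, both among the 4 expanded HOX genes, share a H3K4me3 peak in each EPZ011989 library. It runs from 176103730 to 176108629 in replicate 1 and from 176104154 to 176108729 in replicate 2. The median differences of these 5 lists stayed above 0 under quantile normalization and median subtraction. This does not set the 5 lists apart. It also held for lists that did not pass, among them the neurogenic (272.3 and 435.0 bp) and fibroblast (279.1 and 443.5 bp) lists. In the other lists, adjusted over the list alone, 4 imprinted genes rose, 2 members each of the natural killer ligand, cell cycle, Polycomb, keratinocyte and endothelial lists, and 1 each of the neurogenic, muscle, interferon, FGF, fibroblast and lymphoid lists. Among these were NGFR (252 to 2239 bp), the muscle regulator MYOD1 (672 to 1813 bp), the checkpoint ligand CD276 (407 to 1887 bp) and the NKG2D ligand RAET1G (0 to 1101 bp). Others were the chemokine CXCL12, the cell cycle inhibitor CDKN1C and the desmosome gene DSP. The T cell coreceptor gene CD4 passed too, but its window takes in H3K4me3 peaks at the neighbouring gene GPR162. Its rise is thus largely the one already named at GPR162. Of the 33 tested Merkel cell and neuroendocrine markers 0 passed by limma, over all genes or adjusted over the list alone, with 1 higher and 0 lower at an unadjusted p under 0.05, and their median difference was 0.0 bp, or −67.3 bp after quantile normalization. The 3 tested HLA class II genes, 23 HLA class I genes and 32 housekeeping genes had 0 called either way by limma, with 0, 1 and 1 at an unadjusted p under 0.05.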

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

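The tests of depth, of failed antibody reactions and of extra copies of chromosome 17, the thinning of H3K4me3 peaks to 1 background level, and the use of peak numbers and widths to compare H3K4me3 enrichment, were chosen only after the results were seen.

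Peaks on unplaced or unlocalized sequences, which the comparisons leave out, numbered 29 and 33 in the vehicle H3K27me3 libraries and 2 in EPZ011989 H3K27me3 replicate 1, against 0 in each IgG library. The vehicle H3K4me3 libraries had 5 and 9 such peaks and the EPZ011989 H3K4me3 libraries 10 and 6.

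The near absence of H3K27me3 peaks with EPZ011989 could come from the lower depth of those libraries. At the depth of replicate 1, 176 vehicle replicate 1 peaks would be called with a chance of 95% or more, and 10.8% of them were overlapped (exact 95% interval 6.63 to 16.3), which argues against depth as the whole cause there. At the depth of replicate 2, 55.5 calls would be expected among the 90 strongest peaks and 0 were seen. That number assumes a library that covers the whole genome, while the 22 peaks of replicate 2 lie on 4 chromosomes. On these 4 alone, 10.9 calls would be expected among 17 such peaks and 0 were seen. This argues against depth, with or without missing chromosomes, as the whole cause in replicate 2, but whether that library is complete stays open. The expected calls at both depths rest on a solver that was not tested on broad peaks. The peaks of replicate 1 lay on vehicle H3K27me3 more often than shifted ones (permutation p = 0.000999, the smallest possible). The shifts do not hold gene density or open chromatin fixed, and 23 of these 363 peaks lay on EPZ011989 H3K4me3 peaks. Of the 66 on vehicle regions, 23 lie in the HOXB region. This argues only weakly against a total failure of the antibody reaction in replicate 1. In replicate 2 a total failure stays open (permutation p = 0.159 with 22 peaks). A less efficient reaction in both libraries also stays open, since spike-in values were not analysed here. Loss of the mark through EZH2 inhibition, the difference the design names, remains open beside it.

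The H3K4me3 gains at genes with vehicle H3K27me3 were set against depth, enrichment and replicate differences. With peaks thinned to the lowest solved background, 164 windows were gained, 147 of them shared with the 184, at an odds ratio of 106.5, which argues against background coverage as the whole cause; read depth itself is unknown. EPZ011989 replicate 2 listed fewer H3K4me3 peaks (21086) than vehicle replicates 1 and 2 (22726 and 23804), at a higher background. Its peaks were wider (median 1609 bp against 1453 and 1354 bp), but windows without vehicle H3K27me3 were shorter in it, by a median of 152 and 179 bp, where all 4 libraries had a peak. In EPZ011989 replicate 1 the same windows were longer, by a median of 113 and 92 bp, so a general widening in that library stays open. Between EPZ011989 replicate 2 and vehicle replicate 1, 84.2% of 368 windows with a peak only in EPZ011989 carried vehicle H3K27me3 and 39.2% of those only in vehicle (odds ratio 8.306, Fisher's exact p = 1e-26). Against vehicle replicate 2 the odds ratio was 9.92. Since a gained window needs a peak in both EPZ011989 libraries, this argues against stronger enrichment as the whole cause. Windows shared by the libraries of another pair only carried it at 48.42%, the gained ones at 96.7% (Fisher's exact p = 1.87e-21), although only 3 divisions of 4 libraries exist, too few to give a share under 0.05. As a hypothesis found and tested on the same data, H3K4me3 may extend over windows that have H3K27me3 peaks in vehicle. Nearly all of these had none with EPZ011989, so whether the absence of the peak matters could not be tested. Differences in kind of gene between windows with and without vehicle H3K27me3 were not tested either.

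The peaks left in EPZ011989 replicate 1 crowd in the HOXB region, at 32.9 per Mb (exact interval 20.9 to 49.4). Vehicle regions elsewhere on chromosome 17 held 0.502 per Mb (0.163 to 1.17), so the crowding was not shared by the other vehicle regions of the chromosome. Those regions were not matched to the HOXB region in strength, so extra copies of the whole chromosome stay open. A focal gain was not tested. Chromosome 17, with 2.75% of the length, held 44 of the 363 peaks of replicate 1 and 8 of the 22 of replicate 2. Of the 44, 16 lay on no vehicle H3K27me3 peak, and that density does not count them. Off chromosome 17, vehicle regions with a fold of 10 or more held 0.837 per Mb (0.518 to 1.28), those from 5 to under 10 held 0.151 (0.0607 to 0.311) and those under 5 held 0.167 (0.0862 to 0.291). The excess in the strongest class is what an equal proportional loss would leave nearest the calling limit, but the density did not rise below a fold of 10. Whether the strength of the vehicle signal alone could account for the HOXB count cannot be told apart from a slower loss there: other callable regions held 1.74 per Mb, but that bound was set without equal strength, and only 2 other regions, of 1.32 kb in all, reached the fold of the HOXB region. The pattern is in 1 library, and replicate 2 had 0 peaks there.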

How the results depend on the processing

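The window at a single gene end, the thinning of H3K4me3 peaks and the counts of expanded and contracted windows were chosen only after the results were seen. The log2 ratio of H3K27me3 length (−10.52) and the odds ratio of gains kept their direction under every alternative run, the latter between 12.1 and 106.5, and 9 to 11 lists passed. The log2 ratio of H3K4me3 length, 0.0372, became −0.0744 by number of peaks and −0.0527 by joined domains, and ran from −0.0901 to 0.154 leaving out 1 library; that of IgG ran from −1.95 to 1.56. Lower H3K27me3 windows (5784) were 3301 with the stricter q, where fewer genes are tested, 3598 by quantile normalization and 3210 to 3211 leaving out 1 library; higher ones were 3301 by quantile normalization and 0 to 7 leaving out 1 library. With the replicate number as a block 4555 were lower and 0 higher, and for H3K4me3 0 and 0 by limma (1022 and 134 unadjusted). Higher and lower H3K4me3 windows (0 and 0) were 2 and 4 with windows of 1000 bp, 35 and 0 with 5000 bp, 89 and 7 by quantile normalization and 491 and 32 with no filter. Genes marked in both vehicle and neither EPZ011989 library (7344) were 3642 with the stricter q. Gained windows ranged from 164 to 225, with 108 of 208 under the stricter q, 100 of 225 with a 500 bp overlap, 155 of 198 with 1000 bp and 149 of 188 with 5000 bp among the 184 of the main setting, and from 258 to 377 leaving out 1 H3K4me3 library; lost windows (28) were 12 with the stricter q, 14 with 1000 bp, 13 with a 500 bp overlap and 35 to 116 leaving out 1. Expanded windows (148) were 33 and 242, and contracted ones (5) 0 and 26, with 1000 and 5000 bp; contracted ones were 2 with the stricter q and 8 with thinned peaks. Leaving out 1 H3K4me3 library gave 204 to 672 expanded and 6 to 97 contracted. The gap in Jaccard index within and between treatments (0.0244) ran from 0.0037 to 0.0489. The share of EPZ011989 H3K27me3 peaks on vehicle regions, a mean of 15.9% over both libraries, was 0.0% with the stricter q, which left 0 and 2 peaks, and ran from 13.6% to 20.7% leaving out 1 library, passing in both libraries without vehicle replicate 2 (20.7%) and in the remaining one without EPZ011989 replicate 2 (18.2%). Where no construction is named, the cause was not tested. Among differences of single named genes, 105 values moved by more than the replicate spread and 352 did not, with 0 reversed. For H3K27me3 limma could not be fitted with no filter, with the median difference subtracted or without either vehicle replicate, and no peak was shared by both EPZ011989 IgG libraries; where 1 library stands alone, limma assumes that it varies like the other group. The EPZ011989 H3K27me3 libraries had 0.373 and 0.148 background fragments per base, and no spike-in scaling was made.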

Other observations

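The families, long noncoding RNA genes and chromosome counts below were chosen only after the results were seen.

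At genes of long noncoding RNAs, H3K4me3 gains also lay mostly where vehicle had H3K27me3. Of 18176 such genes, 4377 carried H3K27me3 in both vehicle libraries and 4349 of these in neither EPZ011989 library. H3K4me3 was gained at 107 and lost at 61, and 92 of the gained ones were marked in vehicle (odds ratio 26.7, Fisher's exact p = 1.03e-50). Of the 107, 35 shared a peak with a gained protein-coding window, and 57 of the other 72 were marked (odds ratio 16.6, Fisher's exact p = 2.42e-28). HOTAIR, transcribed from the HOXC cluster, had 10002 H3K27me3-covered bp in both vehicle libraries and 0 with EPZ011989, and 0 H3K4me3-covered bp in vehicle against 1117 and 817 bp in EPZ011989 replicates 1 and 2. SEMA3B-AS1 had 1462 and 1749 bp and LINC02323 1701 and 1481 bp of H3K4me3 in those replicates, against 0 in vehicle.

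Of 18 gene families compared with all other genes for vehicle H3K27me3, the kallikrein proteases were marked at 15 of 15 (adjusted p = 1.91e-06), the SIGLEC receptors at 11 of 12 (adjusted p = 0.000274), the KIR and LILR immune receptors at 20 of 26 (adjusted p = 0.000113) and the ephrins with their receptors at 18 of 23 (adjusted p = 0.000198). Collagens (31 of 44, adjusted p = 3.95e-05) and potassium channels (51 of 83, adjusted p = 2.77e-05) were marked more often too. Histone genes (2 of 85, adjusted p = 2.64e-13), olfactory receptors (77 of 392, adjusted p = 9.36e-13) and ribosomal protein genes (16 of 95, adjusted p = 7.48e-05) were marked less often, all by Fisher's exact test. That test counts neighbouring genes under 1 broad region separately. SIGLEC10, SIGLEC8, SIGLEC12 and SIGLEC6, for example, lie in 1 merged region of 236 kb. For families whose genes lie side by side the p-values therefore overstate the evidence. Zinc finger ZNF genes were marked at 185 of 517, without a difference that passed (adjusted p = 0.688). Chromosome 19, with 1.93% of the length of chromosomes 1 to 22 and X, and 7.26% of the protein-coding genes, held 10.5% and 9.90% of the H3K27me3-covered length of vehicle replicates 1 and 2 and 5.88% and 5.99% of their H3K4me3-covered length.

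The 22 H3K27me3 peaks of EPZ011989 replicate 2 lay on 4 chromosomes, where 100000 draws in proportion to chromosome length reached no fewer than 8. Whether this library was sequenced and aligned in full is unknown.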
